A study of Macaca mulatta with 4 samples.

How the data were processed

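RNA was measured in prefrontal cortex of rhesus macaques (Macaca mulatta) in 4 sequencing libraries, 2 labelled control and 2 labelled sevoflurane, an inhaled general anaesthetic. Per the labels' protocols, sevoflurane was given at about 2.5 to 3%, first near postnatal day 7 and again 14 and 28 days later, for 4 hours each time, and the cortex was taken directly after the third exposure. The labels do not say from which event the later intervals are counted. Per the labels' protocols, total RNA was extracted with Trizol, its integrity was checked on a Bioanalyzer, and libraries were made with standard Illumina protocols. The label of the control libraries gives the agent as none, and how control animals were handled is not given in the sources used here. Handling stress and the time of day of sampling can thus differ between the groups, which bears on glucocorticoid-induced, activity-regulated and clock genes. The labels do not state that the replicates of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

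The values are raw counts of reads per gene, deposited by the authors as 1 table with a column per library. Reads were aligned with HISAT2, per the submitters' processing notes, which give no version. The counting program, genome build, annotation, strand setting and treatment of reads with several matches are not given in the sources used here. Near-identical copies, overlapping genes and antisense partners are therefore uncertain. Genes without a symbol carry a RefSeq gene number behind LOC. A RefSeq gene table of assembly T2T-MMU8v2.0 was used for names alone. No genome sequence was used, and no coordinates are given.

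The table held 33618 genes, of which 8051 had no count in any library. Total counts were 10059944 and 7793757 in control replicates 2 and 3, and 11703857 and 11706115 in sevoflurane replicates 2 and 3. Counts were analysed in R 4.3.3 with edgeR 4.0.16. The filter of edgeR (at least 10 counts at the median depth in the smaller group and 15 in total) left 17693 genes. Libraries were scaled by TMM (trimmed mean of M values), with factors of 1.02 and 0.969 in control replicates 2 and 3 and 1.00 and 1.01 in sevoflurane replicates 2 and 3. Groups were compared by the two-sided quasi-likelihood F test with group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels are CPM, the counts scaled to a common TMM-normalised library size, given as mean ± SD over 2 libraries, and log2 fold changes are sevoflurane against control with their standard error (SE). With 2 libraries against 2, no two-sided exact permutation test can give a p below 0.333, so no test was made on single per-library measures.

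The analysis steps were tested on counts simulated from the 17693 genes at these library sizes, with 200 genes changed. At a 2-fold change 39% of the changed genes were called, and at a 4-fold change 73%. There were 7 calls among the unchanged genes. The median error of the log2 fold change was 0.16 at 4-fold. A change near 2-fold could thus be missed at this depth and number of libraries.

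Before the data were examined, 49 gene lists (processes, cell types, neighbouring regions and Y-linked genes; 1238 genes) were fixed, along with the tests, the alternatives and the rule for naming genes. Of the list genes, 43 were matched through a RefSeq gene number or an older symbol and 57 were not found by name. The 47 lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01. They were tested again with a correlation estimated per list, which leaves 2 residual degrees of freedom, and with fry. For each list, calls are counted over all genes tested and also adjusted over the list alone. Genes are named by 3 parts of the rule. The first takes the 12 largest changes in each direction among called genes with a symbol, a mean of at least 1 CPM and groups that do not overlap. The second takes up to 4 members with the smallest p of each called list, and the third is a fixed set that includes ERMN, TYMS, MBP, MOG, DNMT1, DNMT3A, DNMT3B, FOS, EGR1, ARC, NPAS4, FKBP5, PER1, HBB and GFAP. The rule gave 53 genes, and some single-gene results are not reported here. Other genes named in the text were chosen after their values were seen.

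The alternatives were DESeq2's size factors, library size alone, no filter, a stricter filter (1 CPM in 2 libraries and a mean of 5 CPM), DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, the replicate number as a block, other thresholds, and leaving out each library in turn.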

Results

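Gene expression was measured by RNA-seq in prefrontal cortex of infant rhesus macaques taken directly after the last of repeated sevoflurane exposures, and in control cortex, with 2 libraries per group. Total counts ranged from 7793757 in control replicate 3 to 11706115 in sevoflurane replicate 3, and 20753 to 23224 genes had at least 1 count. The 10 most abundant genes took 2.98% and 3.3% of the counts in control replicates 2 and 3, and 2.58% and 2.49% in sevoflurane replicates 2 and 3. Spearman correlations between libraries were 0.9770 for the control pair and 0.9846 for the sevoflurane pair. Across groups, control replicate 2 had 0.9779 and 0.9801 with sevoflurane replicates 2 and 3, above its value with control replicate 3, which had 0.9698 and 0.9724. No pair agreed within sampling noise. Control replicate 3, the shallowest library, stood apart on the first principal component (52.3% of the variance), at 59.56 against -3.12 for control replicate 2 and -32.02 and -24.41 for sevoflurane replicates 2 and 3.

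The comparison asked which genes differed in infant cortex after repeated sevoflurane, a design with an interest in myelination. Of the genes lower after sevoflurane, 17 were among 29 tested myelin structural genes and 8 among 25 immediate early genes, which neuronal activity switches on. Both lists were lower by camera with its preset correlation. With an estimated correlation (0.59 and -0.01) they had adjusted p = 0.361 and adjusted p = 0.297. MBP, the myelin basic protein, fell from 4700 ± 2150 to 1010 ± 301 CPM (SD, n = 2 per group), a log2 fold change of -2.22 (SE 0.29, adjusted p = 0.0195). EGR1, an activity-induced transcription factor, fell from 226 ± 15.8 to 53.5 ± 8.45 CPM (-2.08, SE 0.15, adjusted p = 0.00169). FKBP5, a co-chaperone of the glucocorticoid receptor induced by glucocorticoids, rose from 2.68 ± 0.895 to 14.9 ± 5.35 CPM (2.49, SE 0.38, adjusted p = 0.0259). Of 17693 genes tested, 11 were higher and 95 lower after sevoflurane, so 89.6% of the 106 calls were lower. Both libraries of one group lay above both of the other for all 106, an arrangement seen in 41.2% of all tested genes and in 33.3% by chance. By at least 2-fold, 10 genes were higher and 81 lower. The count of calls depended on the test, with 59 higher and 215 lower by DESeq2.

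**Figure D1:**
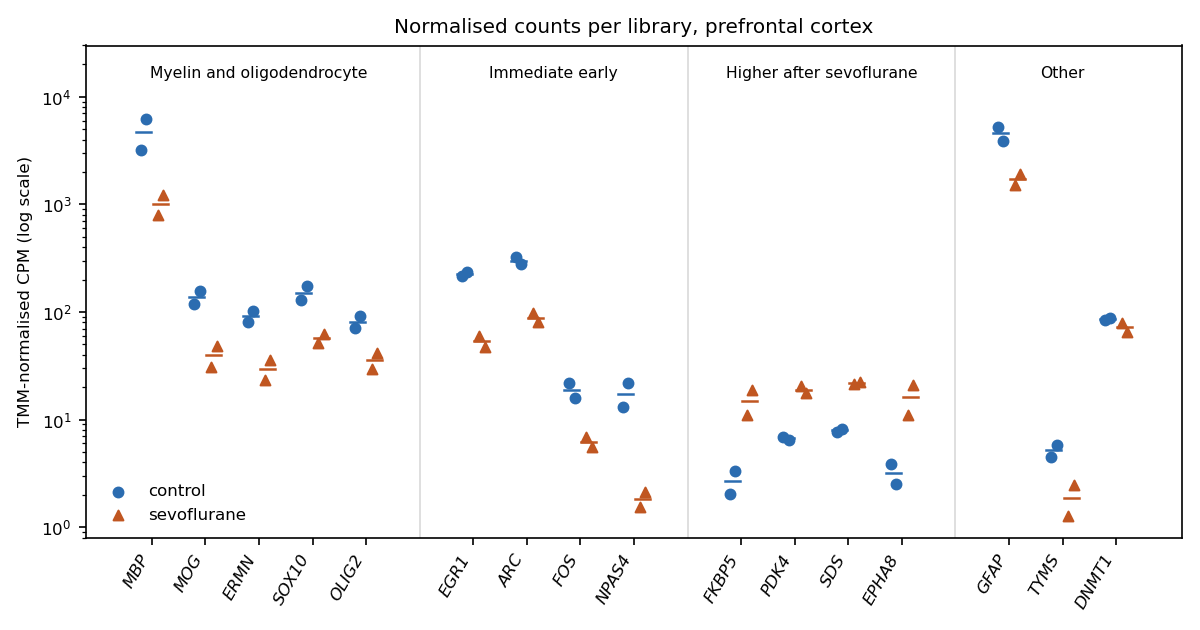
TMM-normalised CPM (log axis) of 16 genes in each of the 2 control libraries (circles) and 2 sevoflurane libraries (triangles), with short lines at the group means. For MBP the group means are 4700 and 1010 CPM and for FKBP5 2.68 and 14.9 CPM, while TYMS and DNMT1 were not called.

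Of 29 tested members of the list of myelin structural genes, 17 were lower, 0 higher and 12 not called (25 lower and 0 higher adjusted over the list alone), with a median log2 fold change of -1.64. The list was lower by camera (adjusted p = 2.59e-77), with adjusted p = 0.361 with an estimated correlation. That estimate was 0.59, far above the preset of 0.01, so the p at the preset overstates the evidence. Myelination is the study's known topic, so this list, ERMN and TYMS are not independent evidence of direction. MOG, a protein of the outer myelin surface, fell by 1.79 on the log2 scale (SE 0.22, adjusted p = 0.0145). ERMN, an oligodendrocyte cytoskeletal protein, fell from 91.4 ± 14.4 to 29.7 ± 9.07 CPM (-1.62, SE 0.22, adjusted p = 0.0197). OPALIN (-1.91), CLDN11 (-1.97), MAG (-2.12), GJB1 (-2.28) and MAL (-2.31) also fell. TSPAN2 was the one member with a positive value (0.45, SE 0.26, adjusted p = 0.65), chosen here after its value was seen.

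Of the 20 mature oligodendrocyte markers, 16 of which are also in the myelin list, 14 were lower and 6 not called (19 lower adjusted over the list alone; median -1.88). Camera gave adjusted p = 9.42e-76, and adjusted p = 0.361 with an estimated correlation of 0.84. Mean deviations of these markers from the mean of the 4 libraries were 0.50 and 1.30 in control replicates 2 and 3, and -1.17 and -0.63 in sevoflurane replicates 2 and 3 (log2). Over the same libraries the deviations of meningeal and perivascular fibroblast markers were -0.01, -1.0, 1.03 and -0.03, and those of a list of white matter and axon tract genes, mostly axonal genes of neurons, were -0.20, 0.31, -0.08 and -0.02. Of 24 oligodendrocyte lineage regulators, 6 were lower and 18 not called (17 lower adjusted over the list alone; median -0.89). This list was lower by camera (adjusted p = 4.74e-33), with adjusted p = 0.361 with an estimated correlation. The transcription factors SOX10 (-1.41) and MYRF (-1.67) fell, as did BCAS1 (-1.76), a marker of newly formed oligodendrocytes, and the receptor GPR37 (-1.31). Of 19 oligodendrocyte precursor markers, SOX10 and OLIG2 (-1.19) were lower and 17 were not called (11 lower adjusted over the list alone; median -0.62). Both called genes are also in the list of lineage regulators, so the precursor list added no called gene of its own. OLIG2 was not called with library size alone (adjusted p = 0.0584) or with no filter (0.0795). Camera gave adjusted p = 8.82e-14, and adjusted p = 0.361 with an estimated correlation. GPR17 (-1.09, adjusted p = 0.0519) and SMOC1 (-0.87, adjusted p = 0.0584) did not pass. Together, 24 of the 95 lower genes belonged to these 4 lists, which held 70 tested genes. ANLN (-2.08), a member of the mature oligodendrocyte list, is among these 24. CDH19 (-2.34), a cadherin in none of the 4 lists, fell too. CDH19 had -1.71 without control replicate 3 and was not called by limma-voom (adjusted p = 0.0931), with library size alone (0.0628) or with no filter (0.0923). With no filter, ANLN (adjusted p = 0.0706) and GPR37 (0.0516) were not called either.

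**Figure D2:**
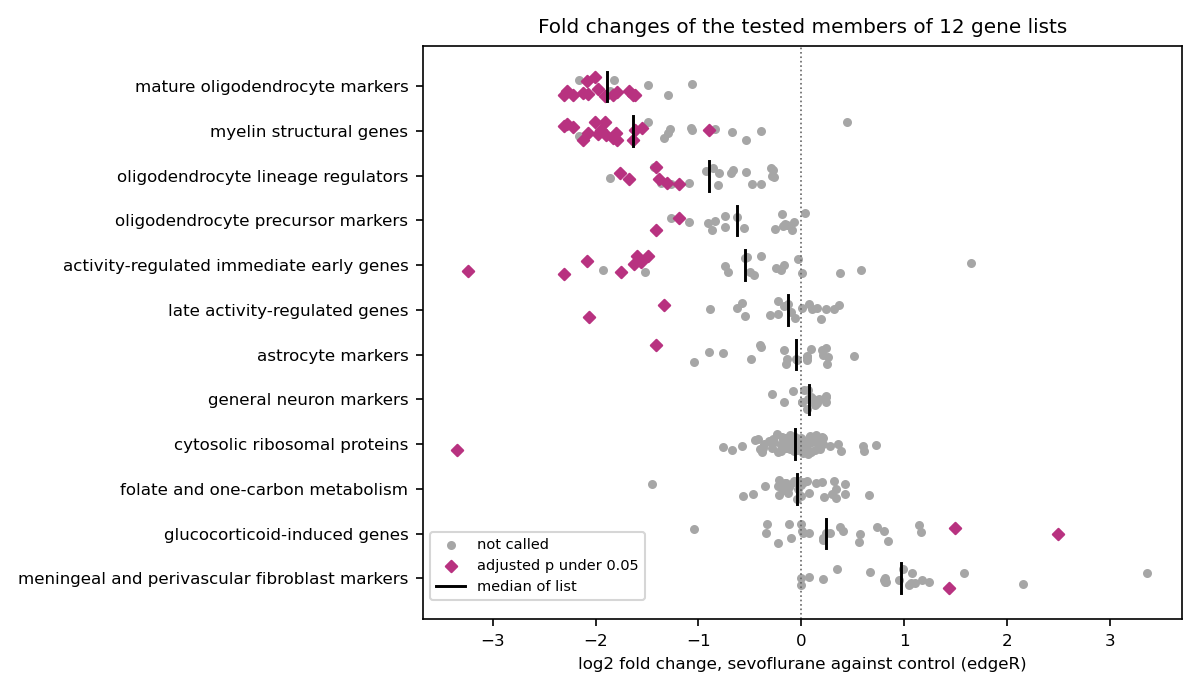
Log2 fold changes (horizontal axis, sevoflurane against control) of the tested members of 12 fixed gene lists, with diamonds for called genes, grey points for the others and bars at list medians. The median is -1.88 for mature oligodendrocyte markers, -0.54 for immediate early genes, 0.08 for general neuron markers and 0.24 for glucocorticoid-induced genes.

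The immediate early genes are transcribed within minutes of neuronal firing. Of 25 tested, 8 were lower, 0 higher and 17 not called (12 lower and 1 higher, MAFF, adjusted over the list alone), with a median of -0.54. Camera gave adjusted p = 3.41e-28, and adjusted p = 0.297 with an estimated correlation. That estimate was -0.01, below the preset of 0.01, so correlation between the genes does not account for the weaker p. Before adjustment over the lists, p was 0.00631 by camera with the estimate and 0.00222 by directional fry (0.0364 and 0.0507 for the myelin list). ARC, a regulator of synaptic strength, fell from 299 ± 30.6 to 88.7 ± 12.4 CPM (-1.76, SE 0.15, adjusted p = 0.0038). NPAS4, a neuronal transcription factor, fell from 17.5 ± 6.06 to 1.83 ± 0.413 CPM (-3.24, SE 0.37, adjusted p = 0.00919). EGR4 (-2.31), FOS (-1.59, adjusted p = 0.0399), DUSP6 (-1.56), NR4A3 (-1.49) and NR4A1 (-1.63, listed as LOC696797) made up the rest of the 8. FOS was not called with library size alone (adjusted p = 0.0623) or with no filter (0.0775). Of 21 late activity-regulated genes, TRIB1 (-2.07) and INHBA (-1.33), a subunit of activin, were lower and 19 were not called (4 lower adjusted over the list alone; median -0.13). Camera gave adjusted p = 0.00216, and adjusted p = 0.762 with an estimated correlation. BDNF, a neurotrophin, had -0.89 (SE 0.21, adjusted p = 0.149) and SST, the neuropeptide somatostatin, -0.62 (SE 0.19, adjusted p = 0.276). DUSP4 (-2.34), a MAP kinase phosphatase, also fell. Without sevoflurane replicate 3 the late list had adjusted p = 0.124, and without sevoflurane replicate 2 INHBA had adjusted p = 0.0846. INHBA was also not called with library size alone (adjusted p = 0.0614) or with no filter (0.0795).

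Of 25 glucocorticoid-induced genes, FKBP5 and PDK4 were higher and 23 were not called (4 higher adjusted over the list alone; median 0.24). Camera gave adjusted p = 2.68e-05, and adjusted p = 0.503 with an estimated correlation. PDK4, a kinase that inhibits pyruvate dehydrogenase, rose from 6.71 ± 0.305 to 19.0 ± 1.96 CPM (1.50, SE 0.24, adjusted p = 0.0322). CEBPD (1.16, SE 0.33, adjusted p = 0.223) and DDIT4 (1.15, SE 0.28, adjusted p = 0.154) did not pass. Other well-known targets in the list were not called either. PER1, which is in the fixed set of named genes, had -0.34 (SE 0.13). Among targets chosen after their values were seen, SGK1 had -1.05 (SE 0.52), TSC22D3 -0.00 (SE 0.17) and ZBTB16 0.08 (SE 0.15). Outside this list EPHA8 (2.30), SDS (1.47), SLC6A13 (1.43), OPRL1 (1.05) and THBS1 (0.88) rose. By limma-voom FKBP5 (adjusted p = 0.0596), SLC6A13 (0.0668) and EPHA8 (0.1) were not called. With no filter, SDS (adjusted p = 0.0489) was called and FKBP5 (0.0532), PDK4 (0.0639), THBS1 (0.0706), OPRL1 (0.075), EPHA8 (0.0795) and SLC6A13 (0.0885) were not. With library size alone, EPHA8 (adjusted p = 0.0602) and SLC6A13 (0.0605) were not called. Without sevoflurane replicate 2, SLC6A13 had adjusted p = 0.14 and THBS1 0.0801, and without sevoflurane replicate 3 OPRL1 had 0.0653.

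Of 22 astrocyte markers, GFAP, the intermediate filament protein of astrocytes, was lower and 21 were not called (4 lower adjusted over the list alone). The list had a median of -0.05 and a mean of -0.18, with camera adjusted p = 0.0248, and adjusted p = 0.775 with an estimated correlation. GFAP fell from 4560 ± 971 to 1710 ± 260 CPM (-1.41, SE 0.16, adjusted p = 0.00928). AGT had -0.90 (adjusted p = 0.0509), ID3 -1.05 (adjusted p = 0.128) and S100B -0.76 (adjusted p = 0.168). Without control replicate 2 this list had adjusted p = 0.198. Of 22 meningeal and perivascular fibroblast markers, SLC6A13, a GABA transporter, was higher and 21 were not called (2 higher adjusted over the list alone; median 0.97). Camera gave adjusted p = 9.75e-09, and adjusted p = 0.775 with an estimated correlation. These markers were thus lowest in control replicate 3 and highest in sevoflurane replicate 2, the reverse of the mature oligodendrocyte markers. SLC13A4 (3.37, SE 0.88), CRABP2 (2.16, SE 0.71) and COL6A2 (1.25, SE 0.45) did not pass. With 1 library left out these values moved widely: SLC13A4 was 1.88 without sevoflurane replicate 2, 2.52 without control replicate 3, 4.11 without sevoflurane replicate 3 and 7.02 without control replicate 2. CRABP2 was 1.53 without control replicate 3 and 3.62 without control replicate 2, and COL6A2 was 0.13 without sevoflurane replicate 2 and 1.87 without sevoflurane replicate 3.

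TYMS, thymidylate synthase of folate metabolism, had 5.16 ± 0.952 CPM in controls and 1.87 ± 0.834 after sevoflurane, a log2 fold change of -1.45 (SE 0.48, 95% interval -2.54 to -0.36, adjusted p = 0.325), and was not called. The DNA methyltransferases DNMT1 (-0.25, SE 0.15), DNMT3A (0.05, SE 0.13) and DNMT3B (0.07, SE 0.45), the clock gene PER1 (-0.34, SE 0.13) and the haemoglobin gene HBB (-0.35, SE 0.37) were not called. RPS15A, a ribosomal protein gene, fell from 40.3 ± 1.35 to 3.96 ± 0.282 CPM (-3.34, SE 0.22, adjusted p = 0.00119), and ribosomal protein genes have near-identical copies whose reads the counting could have split. MOV10L1 fell by 2.97 on the log2 scale (SE 0.49, adjusted p = 0.0373), with -2.08 without control replicate 2. It was not called by limma-voom (adjusted p = 0.0991), with library size alone (0.0602) or with no filter (0.075).

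The other 38 tested lists were not called by camera, and 8 of them held called members. PER2 (-1.71, adjusted p = 0.00435) was lower among 22 circadian clock genes (list median -0.08, adjusted p = 0.21; 3 lower and 1 higher adjusted over the list alone), and NR1D1 had 0.91 (adjusted p = 0.0769). CX3CR1 (-1.03) and SALL1 (-0.93), genes of resident microglia, were lower among 25 microglia and macrophage markers (median -0.02, adjusted p = 0.282; 2 lower and 1 higher adjusted over the list alone). CX3CR1 was also the one lower gene among 21 of complement and synapse pruning (median -0.21, adjusted p = 0.282; 2 lower adjusted over the list alone). CRYAB (-2.07), a small heat shock protein, was lower among 24 heat shock and chaperone genes (median -0.14, adjusted p = 0.186; 2 lower adjusted over the list alone) and among 16 motor and deep-layer cortex markers (median -0.17, adjusted p = 0.213; 1 lower adjusted over the list alone). NFASC (-0.89), also a member of the myelin list and counted there, was lower among 15 genes of white matter and axon tracts (median -0.00, adjusted p = 0.373; 2 lower adjusted over the list alone). RPS15A was the one called gene among 76 cytosolic ribosomal proteins (median -0.07, adjusted p = 0.183; 1 lower adjusted over the list alone). Of 19 acute-phase and reactive astrocyte genes, GFAP was lower and FKBP5 higher (median -0.19, adjusted p = 0.0914; 6 lower and 3 higher adjusted over the list alone). PER2, NR1D1, CX3CR1, SALL1, CRYAB and NFASC were chosen after their values were seen.

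No member was called by edgeR in the other 30 lists, which held 676 distinct tested genes. Of these 676 genes, 76 had an unadjusted p under 0.05 by edgeR, as did 1755 (9.92%) of all 17693 tested genes. Of the 676, 7 were called by DESeq2 (among them AQP1, BHLHE40, DDIT4, IL1R1, ITIH5 and PFKFB3) and 0 by limma-voom. Neuron markers had medians of 0.08 for 18 general neuron genes (adjusted p = 0.277), -0.08 for 16 excitatory (0.736) and 0.09 for 23 inhibitory neuron genes (0.81). Among receptors and channels the medians were 0.06 for 20 GABA-A and glycine receptor genes (adjusted p = 0.277), 0.02 for 35 glutamate receptor genes (0.373), 0.12 for 12 two-pore potassium and HCN channel genes (0.334), 0.06 for 28 voltage-gated channel genes (0.46) and 0.03 for 34 genes of synaptic vesicles (0.972). Metabolic lists had medians of -0.05 for 37 genes of folate and one-carbon metabolism (adjusted p = 0.569), -0.05 for 24 of cholesterol synthesis (0.736), 0.00 for 73 of oxidative phosphorylation (0.879), -0.19 for 14 drug-metabolism enzymes (0.213) and 0.01 for 34 DNA and histone methylation enzymes (0.935). Stress lists had medians of 0.24 for 26 hypoxia genes (adjusted p = 0.0914; 2 lower and 1 higher adjusted over the list alone), -0.10 for 27 of the unfolded protein response (0.46), 0.03 for 29 of apoptosis (0.599), 0.10 for 23 p53 targets (0.409) and -0.08 for 26 antioxidant genes (0.85). Immune and proliferation lists had medians of 0.06 for 31 interferon-stimulated genes (adjusted p = 0.623), 0.10 for 13 cytokine and NF-kB genes (0.142; 1 higher adjusted over the list alone), -0.09 for 33 cell cycle genes (0.409) and -0.11 for 12 replication-dependent histones (0.213).

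Vascular lists had medians of -0.04 for 25 endothelial markers (adjusted p = 0.659; 1 higher adjusted over the list alone) and -0.02 for 15 pericyte and smooth muscle markers (0.859). Ventricle and blood lists had medians of 0.26 for 12 ependymal markers (adjusted p = 0.334), 0.33 for 11 choroid plexus markers (0.402; 1 higher and 1 lower adjusted over the list alone), -0.18 for 6 red blood cell markers (0.409) and 0.86 for 6 neutrophil and lymphocyte markers (0.213). Markers of neighbouring regions had medians of 0.05 for 15 striatal genes (adjusted p = 0.263; 2 higher adjusted over the list alone) and 0.00 for 14 hippocampal and thalamic genes (0.947; 1 higher adjusted over the list alone). Among the lists not called, the median and the mean or the direction of camera differed in sign for inhibitory neurons, apoptosis, DNA and histone methylation, oxidative phosphorylation, hippocampal and thalamic genes, synaptic vesicles, antioxidant genes, and pericytes and smooth muscle. The 2 untested lists were the mitochondrial genome, whose 13 genes had 0 counts in each library, and the Y chromosome, whose 9 genes had 0 or 1 counts per library.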

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

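The counts of lower myelin and immediate early genes were recomputed as alternatives chosen after seeing the data, and the others were planned. All 106 calls kept their sign under each alternative that tested them. All 106 were also called under DESeq2's size factors, the likelihood ratio test, the replicate block and without either control library, 105 of 105 tested by DESeq2 and under the stricter filter, 99 by limma-voom, 98 without sevoflurane replicate 3, 84 without sevoflurane replicate 2, 82 with library size alone and 60 with no filter, which tested 25567 genes. Of the 53 genes chosen by the naming rule, 13 lost their call with no filter, 7 with library size alone and 5 by limma-voom. Genes higher and lower (11 and 95) numbered 3 and 57 with no filter, 137 and 304 by the likelihood ratio test, 59 and 215 by DESeq2, and 33 and 170 at an adjusted p under 0.10. There were 7 higher by limma-voom. With 1 library left out, on 1 residual degree of freedom and with the lone library assumed to vary like the other group, they ranged from 57 to 187 higher and 121 to 420 lower. These were 187 and 420 without control replicate 2, 139 and 248 without control replicate 3, 57 and 121 without sevoflurane replicate 2, and 69 and 180 without sevoflurane replicate 3, and the cause was not tested. The replicate block gave 170 higher and 341 lower genes and 13 lower immediate early genes (8 without it). Whether the shared numbers pair the samples is not known, since no label gives a shared animal and there are 2 pairs. Deviations of same-numbered libraries correlated across 17693 genes with r = 0.0090 (Spearman -0.0116). A correlation over all genes does not exclude an offset shared in particular lists. In both groups, replicate 2 lay above replicate 3 in fibroblast markers and below it in mature oligodendrocyte markers. The immediate early list had no such shared order. Lower myelin genes (17) ranged from 18 to 23 and lower immediate early genes from 9 to 10 with 1 library left out. Of the 9 called lists, 0 remained with an estimated correlation and 0 by fry (directional); the former rests on 2 residual degrees of freedom. In either direction (fry, mixed) 4 lists were called: circadian clock (adjusted p = 0.0108), apoptosis (0.0166), microglia and macrophages (0.0312) and immediate early genes (0.0359). With the replicate block camera called 12 lists. The myelin list had adjusted p = 0.361 and 0.296, and the immediate early list 0.297 and 0.104. With 1 library left out, 11 to 16 lists were called, with 16 without control replicate 3 and 14 without control replicate 2. Log2 fold changes of 3 genes that were not called crossed 0 with 1 library left out: DNMT3A from -0.050 to 0.15, DNMT3B from -0.38 to 0.80 and HBB from -0.85 to 0.34. TYMS had 15 to 46 counts per library, and whether depth kept it from a call was not tested. LOC107000143, with 1 to 57 counts per library, was called at a larger change (4.05, adjusted p = 0.0479).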

Other observations

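The explanations below were tested after the results were seen, except the count of genes over other splits of the libraries. For that count, the bound was written beforehand and a second version without the immediate early genes was added after the result. The genes outside the fixed lists and the rule for naming genes were also chosen after their values were seen.

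Beyond the fixed lists, 55 of the 95 lower genes belonged to no list. Among them APOD (-1.60), a lipid carrier, LPAR1 (-1.51), a lysophosphatidic acid receptor, and ERBB3 (-1.84), a neuregulin receptor, fell. The sphingolipid enzymes ELOVL1 (-1.38) and CERS2 (-1.03) and the transcription factor SOX2 (-1.19) fell too. The lists hold only chosen markers, and the cell type of these genes was not tested. They may thus be part of the fall of the oligodendrocyte lists rather than separate from it. CSF1 (-1.33), a growth factor of microglia, was lower, while CSF1R had -0.41 (adjusted p = 0.441) and P2RY12 -0.33 (adjusted p = 0.565). The macrophage gene CD163 had 1.25 (adjusted p = 0.154). GFAP fell by 1.41 on the log2 scale, whereas the astrocyte transporters SLC1A2 and SLC1A3 had 0.06 and 0.06 (adjusted p = 0.927 and 0.921). AQP4, another astrocyte marker, had -0.49 (adjusted p = 0.367). Of the 22 astrocyte markers, 12 had negative and 10 positive values. Of the 19 acute-phase and reactive astrocyte genes, 11 had negative and 8 positive values, and the list was not called (camera adjusted p = 0.0914). Adjusted over the list alone, 6 were lower and 3 higher. Over all genes, GFAP was called lower and FKBP5 higher. CD44 (-1.21, adjusted p = 0.0945), C3 (-0.92, 0.0681), TNC (-0.60, 0.0658), SERPINA3 (-1.62, 0.193) and CHI3L1 (-1.43, 0.296) were lower but not called. LOC106995557 rose from 3.19 ± 1.14 to 46.7 ± 19 CPM (3.83, adjusted p = 0.00435).

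Of 20 mature oligodendrocyte markers 14 were lower after sevoflurane, with adjusted p = 0.361 for the list with an estimated correlation. A scaling error moves all genes of a library alike and could not account for it. The markers' median lay at -1.88 relative to that of all tested genes (SD 0.33 over the markers). One control library rich in oligodendrocyte RNA could not account for all of it, with a median of -1.53 without control replicate 3. Less white matter or fewer oligodendrocytes in the sampled tissue cannot be told apart from a change of these genes within oligodendrocytes after sevoflurane. The reason is that the tissue share of each library was not measured. Fibroblast markers moved the other way in control replicate 3 and sevoflurane replicate 2 (-1.0 and 1.03, against 1.30 and -1.17). They were alike in control replicate 2 and sevoflurane replicate 3 (-0.01 and -0.03, against 0.50 and -0.63). Set by replicate number, fibroblast markers were higher and oligodendrocyte markers lower after sevoflurane in both numbers. Whether the numbers pair the samples is not known. The spread of the oligodendrocyte markers' fold changes (chi-square p = 0.374) does not decide between tissue share and a change within cells. These markers move together across libraries (estimated correlation 0.84) and their errors are shared.

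Of 25 immediate early genes 8 were lower after sevoflurane and of 21 late activity-regulated genes 2, with adjusted p = 0.297 and adjusted p = 0.762 for these lists with an estimated correlation. Fewer neurons in the sampled tissue would lower general neuron markers as well. Their median log2 fold change was 0.08 (SD 0.14 over the genes, not over samples), against -0.54 for the immediate early list. Mean deviations of the neuron markers were -0.32 and 0.22 in control replicates 2 and 3, and 0.02 and 0.08 in sevoflurane replicates 2 and 3 (log2). The control libraries thus differed in neuron markers, while the immediate early list had 0.35, 0.48, -0.39 and -0.44 in the same order. Cortex was taken directly after the last exposure, with no group after a single exposure or after recovery. An effect of the anaesthetic at sampling thus cannot be told apart from one of repeated exposure. Lower output of the ERK pathway stays open as a hypothesis. A list of 9 ERK output genes (PHLDA1, SPRY2, SPRY4, DUSP4, CCND1, EPHA2, EPHA4, ETV4 and ETV5) had a median of -0.48, with camera p = 5.75e-09, p = 0.0867 with an estimated correlation and p = 0.0673 by fry. This does not decide it, because several of these genes had been seen to be lower before the list was written.

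RPS15A fell by 3.34 on the log2 scale. A shared fall of ribosomal protein genes would need the others to fall, and the median of the other 75 was -0.06 (SD 0.26 over these genes). For differences between single animals, such as variants or gene copies, genes at least 4-fold apart between every library of one pair and every library of the other were counted, with 4 in the real split (EGR4, LOC106995557, NPAS4 and RPS15A) and at most 1 in the splits that mix the groups (LOC106996361). By the bound written beforehand, at least 0.5 of the number in the real split, a value of 1 argues against this explanation. That bound does not decide it, because EGR4 and NPAS4 are immediate early genes that the treatment itself may move. Without them, in the version added after the result, 2 genes remain and 1 meets the bound. A variant shared by both libraries of a group would show in the real split alone, whatever the mixed splits give. Treatment and animal thus cannot be told apart for RPS15A.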
